A study of Homo sapiens with 9 samples.

How the data were processed

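The labels describe 9 libraries from 2 human cell lines. HEK293T, a line of embryonic kidney origin, gave 7 CUT&Tag libraries, a method in which an antibody directs a transposase to cut and tag DNA beside the protein it binds. Jurkat, a leukaemic T cell line, gave 2 ATAC-seq libraries, in which free transposase cuts open chromatin. The CUT&Tag libraries used an antibody to RBPJ in 4 cases and a control IgG in 3. Knockout of FBXO42 was made with lentiviral CRISPR constructs, per the labels' protocols. Groups were taken from the sample titles, with 1 library per group. The libraries titled RBPJ and RBPJK175R both carry the genotype label FBXO42 knockout, and how either form of RBPJ was introduced is not given in the sources used here.

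Each of the 4 RBPJ libraries and each of the 2 ATAC libraries came with a list of called peaks, and these 6 lists were analysed. Values from the 3 IgG libraries were not analysed here. The submitters' processing notes name Trim Galore, Bowtie2, MACS2 and deepTools and the genome build hg38. Their versions and settings, the control library of each list and the threshold for calling a peak are not given in the sources used here. There is 1 list per library, and no pooling of libraries is stated. Each deposited row gives the chromosome, start and end of a peak. The authors' fold per peak is a ratio of the pileup at the summit to the local background. The deposited lists also give the −log10 of a p-value and the −log10 of a q-value. The deposited score was 10 times the −log10 q, rounded down, in at least 99.98% of peaks of every list. The lowest −log10 q was between 1.30 and 1.32 in all 6 lists. The fold, −log10 q and score belong to the peak they were given for. They were used to describe, rank and filter peaks within 1 list only, since ranks from lists of different lengths show no change between them.

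Peaks on chromosomes 1 to 22, X and Y were used, and peaks with the same position in a list were counted once. Coordinates are given 1-based on hg38. Gene positions came from a table of RefSeq genes on GRCh38 that held 59665 genes with 20037 of them protein-coding. That table gives neither strand nor transcripts, which changed the planned analysis in 4 ways. A promoter had been planned as 1 kb around a transcription start. It was replaced by 1 kb around either annotated end of a protein-coding gene, called a gene end below. The 5′ and the 3′ end could not be told apart by this rule, and starts inside a gene, such as the internal start region of RBPJ, were missed. Exons and introns were replaced by the gene span. The planned search for sequence motifs at summits was not run, because no genome sequence was used here. The planned assignment to gene bodies took 10 kb on both sides of the gene.

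Numbers of peaks were compared as the ratio of the second list to the first, with an exact binomial 95% interval. The share of a list's peaks with at least 1 bp in another list was given with a Clopper-Pearson 95% interval. All such intervals cover counting error only. The expected share came from 100 shuffles of the list within its chromosomes with bedtools v2.31.1, with the largest end in the lists or the annotation taken as the chromosome length. Overlap was also taken by decile of the authors' fold within a list and by position. For genes, a peak overlapping the window of 1 kb around a gene end counted. 11 gene lists were fixed: Notch targets, Notch pathway, RBPJ corepressors, chromatin remodellers, T cell genes, B cell and myeloid genes, kidney and epithelial genes, housekeeping genes, ribosomal protein genes, replication-dependent histones and cell cycle genes. All members were found in the annotation but CIR1, which left 21 of the 22 corepressors. The number of members with a peak in the first list only was set among 10000 random gene lists matched on the decile of fold in the first list. With 1 library per group there was no test between conditions, and no p-value was computed.

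The named genes followed a fixed rule. In each comparison and each list, they were the 10 protein-coding genes whose gene end held the peaks with the highest fold among those that overlapped no peak of the other list, with ties broken by −log10 q. The 5 gene-end peaks with the highest fold in the first list that overlapped the other list were added. Members of both Notch lists were included, as were up to 6 members per other list with a peak in 1 list only, by fold. RBPJ and FBXO42 were always included. Results for some genes that the rule selected are not reported here. The gene lists, the named gene rule, the overlap rules and the alternatives said to be planned were chosen before the data were examined.

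Depth was not stated as a read total. The fold and the −log10 p of a peak together fix the reads piled up at the summit and the background under a Poisson model. Whole-number pileups were recovered for at least 99.98% of peaks in every list, within 0.1% of the −log10 p. The lowest background of a list is the genome-wide floor, which is proportional to reads times fragment length, and the shortest peak was taken as the fragment length. The resulting depth was 83.7% of the FBXO42 wild-type library in the FBXO42 knockout RBPJ library, 55.0% of the titled RBPJ library in the titled RBPJK175R library, and 42.4% of the wild-type library in the knockout ATAC library. With equal fragment lengths assumed these shares were 92.1%, 53.4% and 44.2%. Recovery was tested on simulated rows at 3 background levels, and at least 99.99% of pileups came back. The overlap rules were tested on 20000 simulated intervals with 0 errors, and the chance of a call at lower depth on 300 simulated peaks.

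Other settings planned from the start were −log10 q of at least 5 or at least 10, all contigs, merging of peaks within 500 bp, a 50% reciprocal overlap, summits within 250 bp, equal numbers of the strongest peaks, windows of 3 kb, all annotated genes, gene bodies with 10 kb on each side, and ranking by −log10 q. Thinning the first list to the depth of the second, scaling by the floor alone and a summit pileup of at least 10 were added later. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and random steps used the seed 1.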

Results

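The data were lists of called peaks from 6 libraries, 4 of RBPJ CUT&Tag in HEK293T cells and 2 of ATAC-seq in cells labelled Jurkat. RBPJ is the DNA-binding transcription factor of the Notch pathway, and FBXO42 is an F-box protein, a substrate receptor of a ubiquitin ligase. The series asks whether FBXO42 changes DNA binding by RBPJ and the state of chromatin. 3 comparisons followed from the labels: FBXO42 wild type against knockout for RBPJ in HEK293T, RBPJ against the mutant RBPJK175R in FBXO42 knockout HEK293T, and FBXO42 wild type against knockout for ATAC in Jurkat. Each group had 1 library, so there were no replicates and every difference is between 2 libraries.

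The lists differed in length and in the depth behind them. The RBPJ lists held 42656 peaks over 35.4 Mb in FBXO42 wild type, 36877 over 31.2 Mb in FBXO42 knockout, 19913 over 17.3 Mb in the library titled RBPJ and 22691 over 15.8 Mb in the library titled RBPJK175R. The ATAC lists held 31886 peaks over 18.2 Mb in wild type and 20093 over 9.86 Mb in knockout. In the same order, the median number of reads piled up at a summit was 15, 15, 17, 9, 12 and 8. Summits with 5 or fewer reads made up 34.3% of the knockout ATAC list, 13.6% of the wild-type ATAC list and 6.10% of the titled RBPJK175R list. The other 3 lists had none.

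The FBXO42 gene, the target of the knockout, carried a peak at its higher-coordinate end on chromosome 1 in all 6 lists. The peak lay at 16351681 to 16353542 in the wild-type RBPJ list and at 16351999 to 16353368 in the knockout RBPJ list. In the ATAC lists it spanned 16352043 to 16352999 in wild type and 16352220 to 16352884 in knockout. A peak list gives no level of the FBXO42 transcript or protein, so these files do not check the knockout. RBPJ spans 26105449 to 26435131 on chromosome 4 and had no peak at either annotated end in any list. All 6 lists held a peak over the same internal region, from 26318634 to 26322480 in the wild-type RBPJ list and from 26319822 to 26320855 in the knockout ATAC list. A second interval inside RBPJ had far higher pileups in 3 of the 4 RBPJ lists. Its summit at 26430833 held 79022 reads in FBXO42 wild type, 211241 in FBXO42 knockout and 252672 in titled RBPJK175R. At that summit the local background of the titled RBPJK175R list was 198490 reads, which left a fold of 1.27, while the folds were 1745 in FBXO42 wild type and 30150 in FBXO42 knockout. No peak was called there in the titled RBPJ list or in either ATAC list. The origin of the DNA under this summit was not checked, so its pileups and folds are not read as binding of RBPJ.

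**Figure D1:**
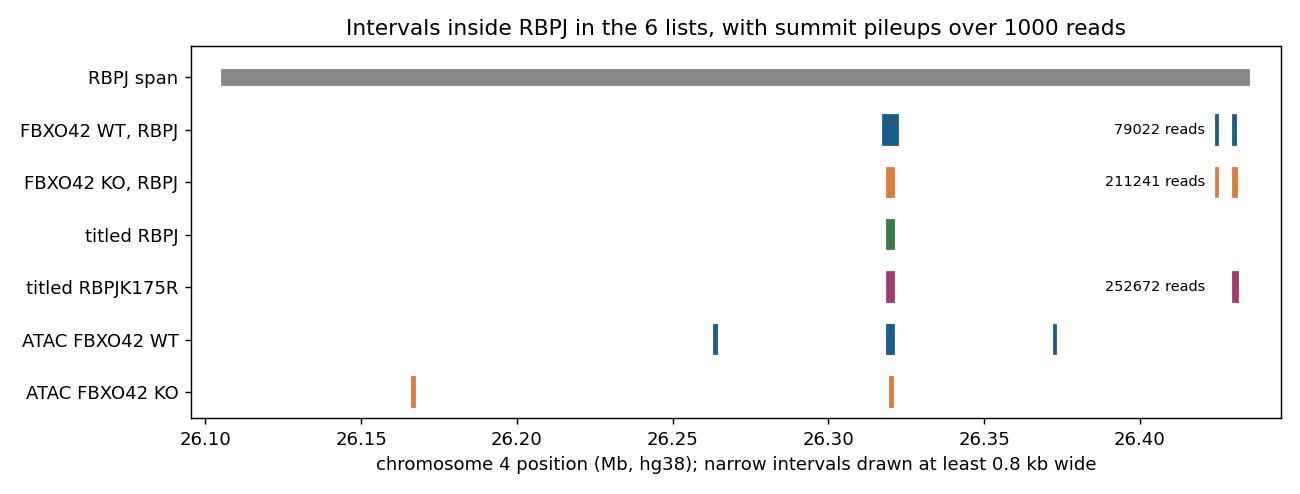
Peaks inside RBPJ in the 6 lists, by position on chromosome 4 in Mb (hg38), with 1 row per library and the gene span in grey. A peak in the same internal region was called in all 6 lists, and the labelled summits held 79022, 211241 and 252672 reads.

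RBPJ peaks lay at a part of the classical Notch target genes in FBXO42 wild-type and in FBXO42 knockout HEK293T cells. The strongest were HES1, HES4 and HEY1, which encode transcriptional repressors switched on by Notch, and MYC, which encodes a growth-promoting transcription factor. In the wild-type list the authors' fold was 116 at HES1, 114 at HES4, 229 at HEY1 and 122 at MYC. Summit pileups at these 4 genes were 416, 957, 789 and 551 reads in wild type and 165, 296, 269 and 140 reads in knockout, at a knockout depth of 83.7% of the wild type.

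Of the 36 Notch target genes, 22 had a gene-end peak in wild type, 23 in knockout and 18 in both, while 9 had none in either list. The share was 61.1% in wild type and 63.9% in knockout, against 54.2% and 41.0% of all protein-coding genes. SOX9, HIVEP3, SHQ1 and PTCRA had one in wild type only, with folds of 5.59, 5.00, 3.24 and 2.70. GATA3, NOTCH3, DTX1, HES2 and CDKN1A had one in knockout only, with folds of 5.14, 4.25, 3.97, 3.58 and 2.95. The 4 targets with a peak in wild type only stood at percentile 38.2 of random lists of like fold, whose median was also 4. Among the 39 Notch pathway genes, 28 had a gene-end peak in wild type, 24 in knockout and 20 in both. MAML3, which encodes a Notch coactivator, held 250 reads at its summit in wild type and 61 in knockout. PSENEN, a subunit gene of the gamma-secretase that cleaves Notch, had a peak in both lists. PSEN2, of the same enzyme, was called in wild type only with a fold of 11.6, as were the receptor gene NOTCH2 at 7.94, the coactivator gene MAML2 at 7.35, and FBXW7, the gene of an F-box protein that acts on cleaved Notch, at 4.08.

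All 21 RBPJ corepressor genes had a gene-end peak in wild type and 16 had one in knockout. Those called in wild type only were CTBP1, FHL1, HDAC3, KDM5A and HDAC2, with folds from 8.27 to 3.11. Chromatin remodeller genes had gene-end peaks in 31 of 32 cases in wild type and 29 in knockout, and BPTF and INO80 were called in wild type only. Cell cycle genes numbered 29 of 30 in wild type and 25 in knockout, without CCND2, AURKA, CCNA2 and BUB1. For ribosomal protein genes the numbers were 76 of 86 and 63, and RPL39L had the highest fold of those in wild type only, 10.7. Replication-dependent histone genes numbered 45 of 68 and 39, without H3C10, H2AC18 and 4 others. Housekeeping genes numbered 13 of 16 and 11, without SDHA and B2M. Among genes of other tissues, 9 and 6 of 36 T cell genes, 6 and 4 of 19 B cell and myeloid genes, and 8 and 7 of 16 kidney and epithelial genes had a gene-end peak in wild type and in knockout. Over all 20037 protein-coding genes these numbers were 10852 and 8223, with 7367 in both.

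The gene-end peaks with the highest fold that overlapped no peak of the knockout list were at OGDH, a Krebs cycle enzyme gene, with a fold of 25.9, followed by ZNF280C at 24.9 and POLR2J, an RNA polymerase subunit gene, at 23.01. The CCR4-NOT subunit gene CNOT11, the chemokine receptor gene CXCR4, PHF20, THOP1, CABCOCO1 and the Hedgehog coreceptor gene CDON followed, down to a fold of 18.8. Each lay in the strongest 3.28% of the wild-type list. The PHF20 peak was also called in the titled RBPJ list, with a fold of 21.3, and that library carries the FBXO42 knockout label. Gene-end peaks in the knockout list alone ran from GAGE13 at 10.6 and DDT at 10.3 through IBA57, TFAP2E, MISP3, LOC124904417, ASPG and RAD21L1 to LOC124904532 at 7.53. The gene-end peaks with the highest wild-type fold among those present in both lists were on chromosome X at POLA1, HCFC1, AMOT and UPF3B, with wild-type folds of 334, 314, 263 and 234, and at HEY1 on chromosome 8.

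The knockout list held 0.865 times as many peaks as the wild-type list (95% interval 0.853 to 0.877) and covered 0.882 times the length. Of the wild-type peaks, 32.1% (31.7 to 32.6) overlapped a knockout peak, against 2.93% for shuffled peaks. Conversely 38.1% (37.6 to 38.6) of knockout peaks overlapped the wild-type list. The overlap rose with strength, from 17.0% in the lowest fold decile of wild-type peaks to 90.1% in the highest, and from 29.3% to 94.6% for the knockout list. Peaks at gene ends were overlapped in 56.8% of wild-type cases and 77.9% of knockout cases. Elsewhere the shares were 24.4% and 28.02%. Gene ends held 23.8% of wild-type and 20.2% of knockout peaks. A further 45.0% and 49.2% lay within genes away from their ends, and the remainder, 31.2% and 30.6%, between genes. With a −log10 q of at least 10 in both lists, the ratio of peak numbers was 0.495, and the share at gene ends differed by 1.39 percentage points, knockout minus wild type, instead of −3.62. The ratio of peak numbers ran from 0.459 on chromosome 3 to 1.43 on chromosome 21, with 17 of the 23 chromosomes compared below 1 and an SD of 0.46 on the log2 scale.

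**Figure D2:**
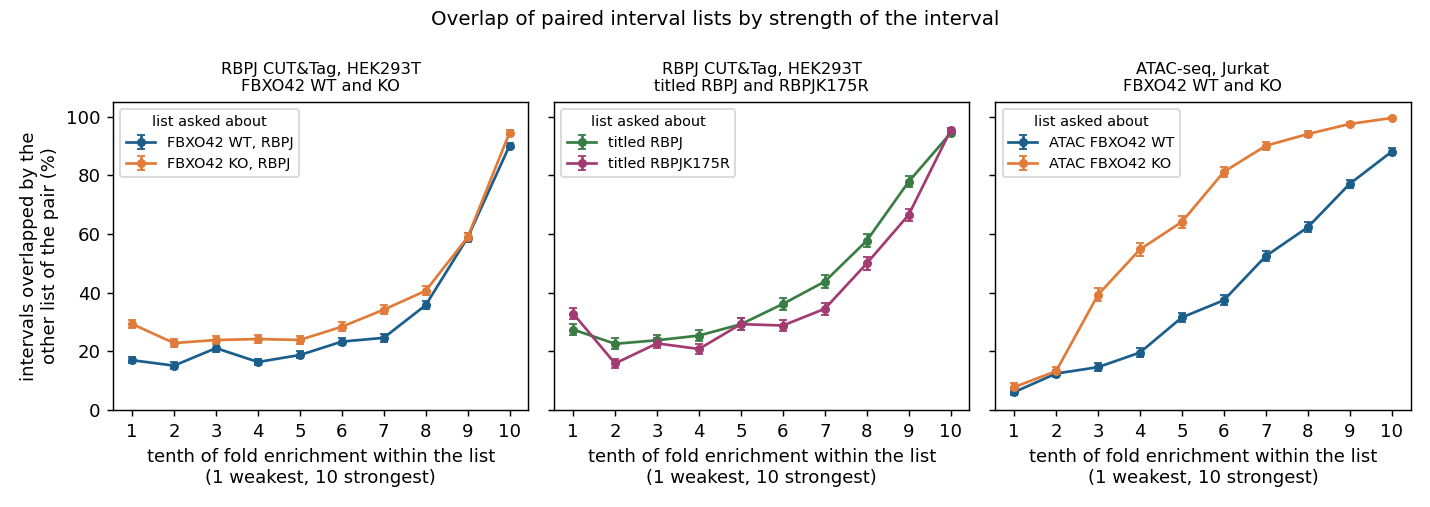
Share of each list's peaks that overlapped the other list of its pair, in percent, by decile of the authors' fold within the list. Bars are 95% Clopper-Pearson intervals, and every highest decile lies between 88.0% and 99.5%.

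**Figure D3:**
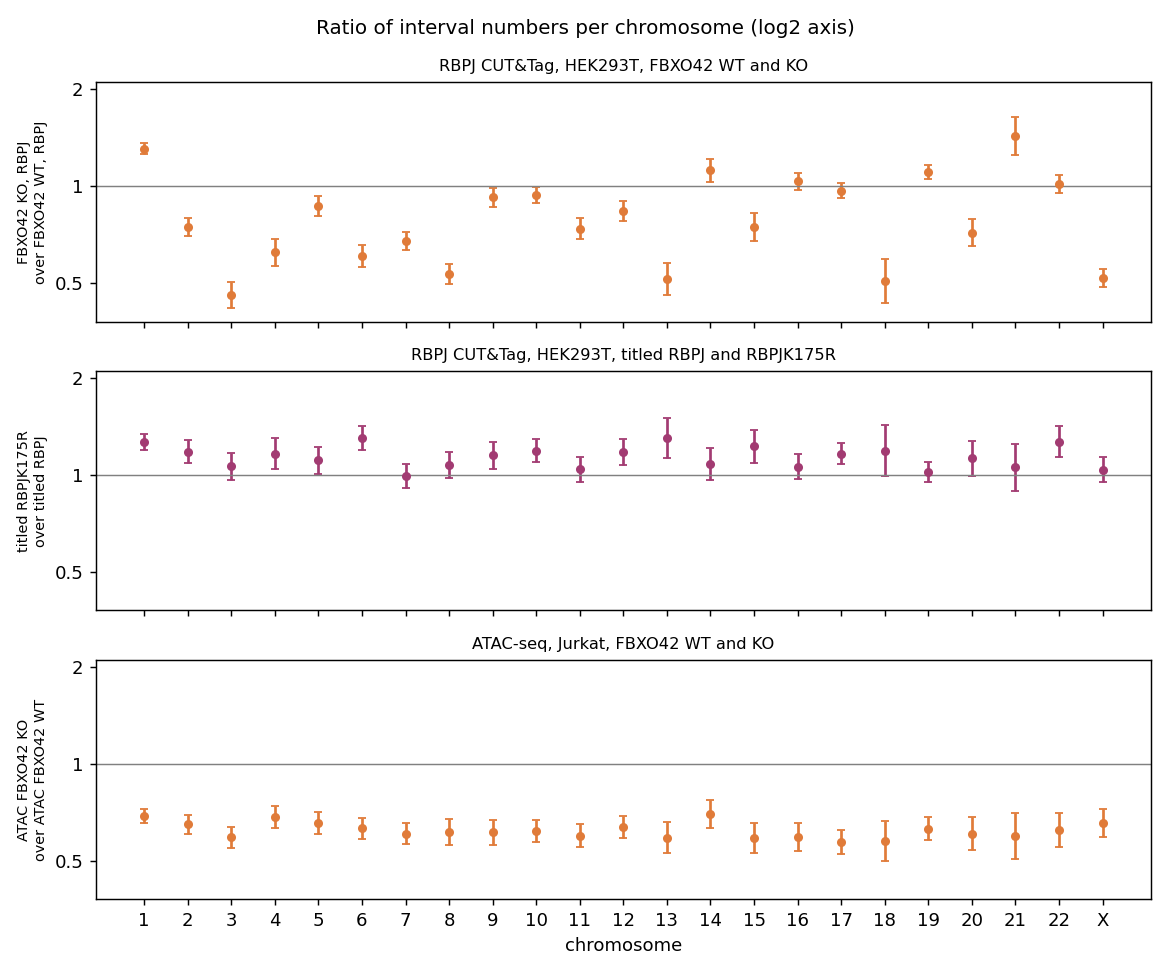
Number of peaks in the second list over the first for each chromosome, on a log2 axis with 95% binomial intervals. The RBPJ pair by FBXO42 genotype ranged from 0.459 to 1.43, and the ATAC pair from 0.572 to 0.700.

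In FBXO42 knockout cells, the libraries titled RBPJ and RBPJK175R shared their strongest sites, including those at Notch target genes. The series names polyubiquitination of RBPJ, and the mutant has arginine in place of a lysine. At a depth of 55.0% of the RBPJ library in the RBPJK175R library, HES1 held 150 reads at its summit in the RBPJ list and 45 in the RBPJK175R list. HEY1 held 214 and 49. MYC, with 130 and 44, and ID3, the gene of an inhibitor of DNA-binding factors, with 41 and 38, had gene-end peaks in both lists. Their gene-end peaks with the highest pileup did not overlap between the lists, so those counts are not read as the same site. At PSENEN the summit pileups were 300 and 189.

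Of the 36 Notch targets, 19 had a gene-end peak in the RBPJ list, 16 in the RBPJK175R list and 15 in both. NOTCH1, JAG1, SNAI1 and IGF1R were called in the RBPJ list only, with folds from 5.33 to 6.70, and SOX9 in the RBPJK175R list only, with a fold of 4.04. These 4 targets stood at percentile 44.4 of random lists. Of the 39 Notch pathway genes, 18 had a gene-end peak in the RBPJ list, 12 in the RBPJK175R list and 11 in both. Besides NOTCH1 and JAG1, those in the RBPJ list only were DLL3, MIB1, NUMBL, PSEN2 and RFNG, and NCSTN was in the RBPJK175R list only.

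RBPJ corepressor genes had gene-end peaks in 16 of 21 cases with RBPJ and 12 with RBPJK175R; TLE2, with a fold of 7.39, led those in the RBPJ list only. Chromatin remodeller genes numbered 24 of 32 and 19, without PBRM1 and EZH2 among others in the RBPJK175R list. T cell genes numbered 7 of 36 and 3, B cell and myeloid genes 4 of 19 and 2, and kidney and epithelial genes 6 of 16 and 4, of which CDH2 had the highest fold of those in the RBPJ list only, 10.1. Housekeeping genes numbered 12 of 16 and 9, without GUSB, ACTB and SDHA. For ribosomal protein genes the numbers were 50 of 86 and 48, and for cell cycle genes 22 of 30 and 21. Replication-dependent histone genes were the only list with more members in the RBPJK175R list, 32 of 68 against 28, with 24 in both; H1-3, at a fold of 5.76, was among the 8 in that list only, and H2AC7, H2BC7 and H3C4 shared 1 peak. The 32 genes were covered by 21 peaks and the 28 by 19. Over all protein-coding genes the numbers were 7660 and 5866, with 4938 in both.

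**Figure D4:**
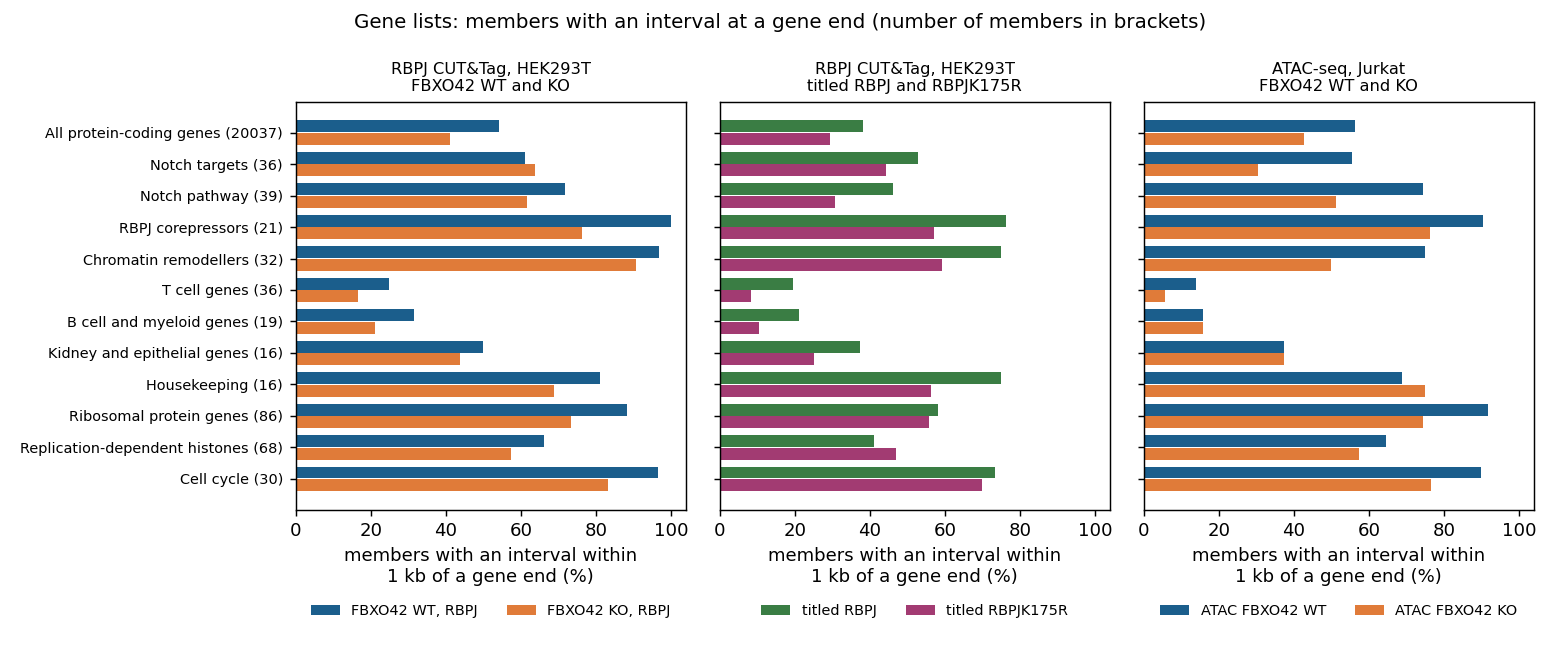
Share of the members of each gene list, in percent, with a peak within 1 kb of a gene end, for both lists of each comparison. Bars start at 0, and the Notch targets stood at 61.1% and 63.9%, 52.8% and 44.4%, and 55.6% and 30.6%.

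The gene-end peaks with the highest fold and no counterpart in the RBPJK175R list were at PHF20, with a fold of 21.3, GPR89B, the Ras regulator gene RASA2, ACOT7 and the NF-kappaB subunit gene RELA at 16.3. NAP1L4, COQ10A, a peak shared by AGPAT1 and RNF5, and DCUN1D2 at 14.6 followed. In the RBPJK175R list alone, a peak between CCHCR1 and TCF19 had a fold of 15.5, followed by the centromere protein genes CENPC at 13.7 and CENPH at 10.9, with ATXN7L3B at 11.5 between them. HELB, RBBP9, ZNF585A, TARS2 and the cyclin gene CCND3 closed that list at 9.29. The gene-end peaks present in both lists were led by a peak between NUDCD1 and ENY2 at a fold of 127 in the RBPJ list, then PCF11, GSK3A and MGRN1.

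The RBPJK175R list held 1.14 times as many peaks as the RBPJ list (1.12 to 1.16) and covered 0.916 times the length. With a −log10 q of at least 5 in both lists the ratio was 0.798, and with at least 10 it was 0.627. With the RBPJ list thinned to the depth of the RBPJK175R library it was 1.325. RBPJK175R peaks overlapped 43.8% (43.1 to 44.5) of RBPJ peaks, against 1.53% for shuffled peaks, and RBPJ peaks overlapped 39.7% (39.04 to 40.3) of RBPJK175R peaks. In the highest fold decile these shares were 94.3% and 95.3%. Gene ends held 32.2% of RBPJ and 21.5% of RBPJK175R peaks. Those were overlapped in 58.8% and 78.2% of cases, and peaks elsewhere in 36.7% and 29.1%. The ratio of peak numbers varied little between chromosomes, from 0.995 on chromosome 7 to 1.302 on chromosome 6, with an SD of 0.12 on the log2 scale.

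In the ATAC libraries, 10 of 36 Notch target genes had an open gene end in the wild-type ATAC list and in the knockout list, 10 in the wild-type list only and ID3 in the knockout list only. HES4, HEY1, HEY2, HES7, DTX4, ID1, JAG1, SHQ1, SOX9 and TSPAN15 were the genes in both lists. MYC, HES1, HEYL, NOTCH1, ID2, TRIB2, HES2, HIVEP3, IGF1R and BCL2, a gene that blocks cell death, were in the wild-type list only. The wild-type summit pileup was 36 reads at MYC, 29 at HES1 and 26 at HEYL, and the knockout library had 42.4% of the wild-type depth. The 10 targets in the wild-type list only stood at percentile 73.9 of random lists of like fold, whose median was 9.

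Notch pathway genes with an open gene end numbered 29 of 39 in wild type and 20 in knockout, and all 20 were in both lists. NUMBL, with a wild-type fold of 10.4, KAT2B at 7.51 and MAML2 at 7.34 led those in the wild-type list only. Housekeeping genes numbered 11 of 16 in wild type, and all 11 were also in the knockout list, with HPRT1 added. RBPJ corepressor genes numbered 19 of 21 and 16, without FHL1, RCOR1 and TLE2. Chromatin remodeller genes numbered 24 of 32 and 16, without SUV39H1, CTCF, EP400 and 5 others. T cell genes numbered 5 of 36 and 2, without MYB, SATB1 and ZAP70, and these low numbers leave the T cell identity given by the label unchecked. Of B cell and myeloid genes the same 3 of 19 were in both lists, and 6 of 16 kidney and epithelial genes were in each list. Ribosomal protein genes numbered 79 of 86 and 64, replication-dependent histone genes 44 of 68 and 39, and cell cycle genes 27 of 30 and 23, without MCM5, MCM2, RB1 and CCND2. Over all protein-coding genes the numbers were 11289 and 8559, with 8269 in both. The number of members in the first list only lay below percentile 1 of random lists of like fold for 3 of the 11 lists in each comparison. By FBXO42 genotype in RBPJ these were histone genes at 0.015, chromatin remodeller genes at 0.14 and ribosomal protein genes at 0.755. For RBPJK175R they were histone genes at 0.14, ribosomal protein genes at 0.27 and cell cycle genes at 0.445, and in ATAC histone genes at 0.005, housekeeping genes at 0.12 and ribosomal protein genes at 0.78. Histone genes that share a peak were counted as separate members, so their percentiles do not rest on independent genes.

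DTX2, a gene of the Deltex family of ubiquitin ligases that act on Notch, had the gene-end peak with the highest fold absent from the knockout list, 14.7. RPAP1, ZNF780A, BTN3A2, RAB39B, PDZD2, CFAP263, PCBP2, TMEM219 and USE1 followed, from 14.3 to 12.4. The highest fold in the knockout list alone was at MSH5, a meiotic homologue of mismatch repair genes, at 10.2. LOC124903544, RAPH1, the nuclear pore gene SEH1L, PLPBP, a peak between CCHCR1 and TCF19, HNF4G, and a peak shared by TMEM35B and ZMYM6 followed, down to 7.82. Among the gene-end peaks with the highest wild-type fold present in both lists were TMEM191C, SEC23B and DELE1, with folds from 19.00 to 17.7.

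The knockout ATAC list held 0.630 times as many peaks as the wild-type list (0.619 to 0.641) and covered 0.542 times the length. Knockout peaks overlapped 40.2% (39.6 to 40.7) of wild-type peaks, against 0.771% for shuffled peaks, and 64.2% (63.5 to 64.8) of knockout peaks overlapped the wild-type list. The highest fold decile was overlapped in 88.0% of wild-type and 99.5% of knockout cases, and the lowest in 6.15% and 7.86%. At gene ends, 66.2% of wild-type and 94.0% of knockout peaks were overlapped, and elsewhere 27.9% and 47.2%. Gene ends held 32.1% of wild-type and 36.2% of knockout peaks. With equal numbers of the strongest peaks, the knockout minus wild-type difference in that share was −7.90 percentage points instead of 4.14, and with a −log10 q of at least 10 the ratio of peak numbers was 0.310. All 23 chromosomes had fewer knockout peaks, from 0.572 on chromosome 17 to 0.700 on chromosome 14.

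Across comparisons, RBPJ CUT&Tag peaks in HEK293T coincided with ATAC peaks of the libraries labelled Jurkat far more than shuffled peaks did, and the cell line of the ATAC libraries rests on the label alone. The wild-type RBPJ list overlapped 45.0% of wild-type ATAC peaks, against 2.24% when shuffled, and the FBXO42 knockout RBPJ list overlapped 28.2%. The titled RBPJ list overlapped 28.4% and the titled RBPJK175R list 21.97%. Among RBPJ lists, 54.7% of titled RBPJ peaks lay in the FBXO42 wild-type list and 49.6% in the FBXO42 knockout list. For titled RBPJK175R these shares were 39.03% and 38.05%. The control library of each list is not given in the sources used here, so overlaps alone are compared between the 2 RBPJ pairs.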

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

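Thinning to equal depth, scaling by the floor alone and the summit pileup of at least 10 were chosen after seeing the data, and all other alternatives came from the plan. The 4 settings planned for the motif search were not run, since the search itself was not. In all, 337 values were recomputed. The ratio of peak numbers stayed below 1 in both FBXO42 comparisons under the 6 alternatives run for it, between 0.495 and 0.948 for RBPJ and between 0.310 and 0.914 for ATAC. For RBPJK175R against RBPJ, thinning gave 1.325, and 1.349 with equal fragment lengths. Peaks of the first list at gene ends were overlapped more often than its others under each alternative run in all 3 comparisons. They were also stronger, with a median fold of 5.77 against 3.97 elsewhere in the wild-type RBPJ list. The medians were 5.85 against 4.87 in the titled RBPJ list and 6.82 against 5.11 in the wild-type ATAC list. No alternative held the fold fixed, so position was not told apart from strength. Except where a setting's construction shows it, such as fewer peaks left or a stricter overlap, the cause was not tested. In what follows, values are in the order RBPJ by FBXO42 genotype, RBPJ against RBPJK175R, and ATAC, and overlaps give the first list and then the second.

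With a −log10 q of at least 5 in both lists, overlaps were 37.5% and 57.1%, 47.9% and 61.5%, and 41.3% and 91.6%. The ratio of RBPJK175R to RBPJ peak numbers fell below 1, to 0.798. The share at gene ends differed by −7.63 points for RBPJK175R and 14.1 for ATAC, and the excess overlap at gene ends was 25, 13.8 and 28.9 points. In ATAC, 4 Notch targets were in both lists and the SD over chromosomes was 0.16. With at least 10, the ratios of peak numbers were 0.495, 0.627 and 0.310 and of covered length 0.520, 0.567 and 0.264. Overlaps were then 41.5% and 85.04%, 51.8% and 83.8%, and 29.2% and 94.01%, and gene-end shares differed by 1.39, −3.46 and 11.1 points. With at least 5 in the list asked about alone, overlaps were 51.5% and 65.2%, 63.9% and 70.8%, and 60.2% and 95.2%. With a summit pileup of at least 10 there, they were 35.6% and 40.8%, 45.6% and 67.2%, and 58.9% and 96.6%.

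A 50% reciprocal overlap gave 17.3% and 20.04%, 29.8% and 26.2%, and 30.5% and 48.4%, with an excess at gene ends of 24.2, 19.9 and 30.9 points. Summits within 250 bp gave 20.6% and 23.8%, 29.8% and 26.2%, and 32.5% and 51.6%. Equal numbers of the strongest peaks gave 35.6% and 36.8%, 42.1% and 43.3%, and 58.3% and 58.8%. Gene-end shares then differed by −6.26, −9.13 and −7.90 points, a change of sign for ATAC, and the excess was 31.1 points for RBPJ by genotype and 27.3 for ATAC. Windows of 3 kb gave differences of −1.84, −12.00 and 2.64 points and an excess of 28.04, 16.3 and 33.3 points. Gene bodies with 10 kb on each side put 28, 23 and 20 Notch targets in both lists, and 1 in the wild-type RBPJ list only.

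Of 180 values for the other gene lists, 123 stayed within 1.5 times the reported number, and all 16 overlaps across comparisons moved beyond counting error. The named genes depended on ranking by fold. Ranked by −log10 q, 6, 1 and 6 of the 10 named in the first list only were still named. The same held for 6, 8 and 7 of the 10 in the second list only, and for 1, 2 and 2 of the 5 in both. Scaling by the floor alone changed the sign of the median RBPJK175R pileup ratio at shared sites, from −0.03 to 0.00855 on the log2 scale. Depth limits the ATAC comparison most: at the knockout depth, 69.0% of wild-type ATAC peaks would be expected to be called, against 91.2% of wild-type RBPJ peaks and 86.0% of titled RBPJ peaks.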

Other observations

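All tests in this part were chosen after the data had been seen. The simulation error of 0.29 set beside the percentile of the Notch targets was applied after that percentile was known, as was the rule that a correlation must hold without each chromosome in turn. The test of whole-chromosome copy number replaced one on the spread between windows of a chromosome, which could not decide it.

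A core of peaks was called in all 4 RBPJ lists. Whether RBPJ binds there was not tested, since no motif search was run and the IgG libraries were not analysed. It held 5310 of the 42656 FBXO42 wild-type peaks, or 12.4% (12.1 to 12.8), of which 58.3% lay at gene ends and 84.9% overlapped a wild-type ATAC peak. Sites present in the FBXO42 wild-type lists of RBPJ in HEK293T and of ATAC and absent from the 2 matching knockout lists numbered 2602, led by one on chromosome 17 at 13994311 to 13998414 between HS3ST3A1 and COX10, one on chromosome 12 at 12319155 to 12320633 between LRP6, a Wnt coreceptor gene, and MANSC1, and one within MLLT3. Each of these 3 was called in at least 1 of the titled RBPJ and RBPJK175R lists, which also carry the FBXO42 knockout label. The opposite pattern was seen at 125 sites. The knockout libraries had 83.7% and 42.4% of the wild-type depth and no expected number was computed, so neither count measures loss or gain.

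Summit pileups scaled to depth were compared at gene ends with a peak in both lists of a pair. Without a spike-in this scale is relative to each library's own total. In FBXO42 knockout, 15 of 16 Notch targets lay lower than in wild type, with a median log2 difference of −1.01, against −0.75 for random lists matched on wild-type pileup and −0.66 over 6396 protein-coding genes, of which 5746 lay lower. MYC stood at −1.72, HEY2 at −1.60, HES4 at −1.44, HEY1 at −1.30 and HES1 at −1.08, while JAG1 stood at 0.26. The random lists were not matched on chromosome. MYC and HEY1 lie on chromosome 8, which had the lowest median of any chromosome at the stronger shared sites, −1.09. HES4 lies on chromosome 1, where that median was −0.55. The pathway gene MAML3 stood at −1.78. Scaling by the floor alone moved the median over shared RBPJ sites from −0.46 to −0.60. All 23 cell cycle genes compared were lower, with a median of −0.999 at percentile 0.25 of random lists of like pileup, whose median was −0.69, and chromatin remodeller genes had a median of −0.56 at percentile 84.4, among 8 lists ranked in each comparison. For RBPJK175R against RBPJ, the Notch targets had a median of −0.26 at percentile 35.7, from −1.27 at HEY1 and −0.88 at HES1 to 0.14 at HES7 and 0.40 at TSPAN15, and the pathway gene MAML3 stood at −0.97. For ATAC their median was 0.20, at percentile 40.4, while chromatin remodeller genes had a median of −0.05 at percentile 2.49 and Notch pathway genes 0.50 at percentile 97.02.

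The first pattern weighed was the shorter knockout ATAC list. Lower signal was not seen at sites called in both libraries. Depth-scaled summit pileups there were higher in knockout, by a median of 0.31 on the log2 scale, by 0.28 in the stronger 50%, and by 0.25 with scaling by the floor alone. Sites that fell below a call in the shallower knockout library are left out, which raises these medians. They therefore cannot decide against lower signal over all wild-type sites. Lower depth is a candidate explanation for the number of peaks, as the knockout list held 0.914 times the 21986 peaks expected from the wild-type list at the knockout depth. This compares totals and does not show that the same peaks were called. A knockout peak overlapped 12811 wild-type peaks, and 7202 knockout peaks, with a median summit pileup of 4 reads, overlapped no wild-type peak. A loss of particular sites beyond depth also stays open. Of 4973 wild-type peaks with a chance of at least 0.99 of a call at that depth, 92.6% overlapped a knockout peak and 367 did not. For RBPJ by FBXO42 genotype 47.2% of 23520 such peaks were overlapped, and for RBPJK175R 77.2% of 6860. The chance treats the second library as a subsample of the first. It leaves out the variation of a separate library and is therefore too high, so these shares do not measure loss beyond depth. The FBXO42 genotype itself stays untested with 1 library each.

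The second pattern was a lower RBPJ summit pileup in FBXO42 knockout, with a ratio of peak numbers that was uneven over chromosomes. At 8791 shared sites the depth-scaled pileup had a median log2 difference of −0.46, and −0.73 in the stronger 50%, which argues against depth alone. The median was −0.65 at gene ends and −0.16 elsewhere. Sites elsewhere were weaker, with median pileups of 24 and 19 reads in wild type and knockout, against 65 and 33 at gene ends. Sites not called in both lists are left out, which weighs most on weak sites, so position is not told apart from strength. The median difference was −0.41 in 10 Mb windows with at least 67 protein-coding genes and −0.57 in the others, which argues against a trend with gene density as the whole cause of the lower pileup. Copy number of whole chromosomes stays a candidate explanation for the unevenness, but its test cannot single it out. Over 23 chromosomes the ratio of peak numbers had a rank correlation of 0.743 with the pileup ratio at the stronger shared sites (0.710 to 0.799 without each chromosome in turn). Both ratios come from the same reads, so any difference between chromosomes would make them rise together. The correlation was 0.471 for RBPJK175R against RBPJ and 0.290 for ATAC. The SD between windows of 1 chromosome, 0.49 beyond counting error, shows that copy number of whole chromosomes would not be the only source. Whether a trend with gene density accounts for part of the unevenness stays open: its rank correlation with the ratio over windows, which are not independent, had a median of 0.31 over 19 chromosomes and was above 0 in 17, but without any of 9 single chromosomes, such as chromosome 1, it was 0.299, under the bound of 0.3. The lower pileup was not confined to Notch targets, as 5746 of 6396 protein-coding genes lay lower. Whether Notch targets fell further than genes of like pileup cannot be told. Their median stood at percentile 2.3, within 0.29 of the bound of 2.5. That 0.29 is the error of the random draws only and leaves out the spread of a median of 16 genes. Cell cycle genes stood at percentile 0.25, so a low percentile was not particular to Notch targets. The FBXO42 genotype stays untested.

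The third pattern was the low number of T cell genes with a gene-end peak in the ATAC libraries labelled Jurkat, 5 of 36 in wild type and 2 in knockout. Promoters outside the gene-end windows are argued against as the whole cause. In the wild-type ATAC list, 47.2% (30.4 to 64.5) of T cell genes had a peak in the gene or at its ends. This share was 68.4% for all protein-coding genes. For 19 B cell and myeloid genes it was 26.3%, which runs toward the label. Other values of this measure do not run toward the label. In the same list, 12 of 16 kidney and epithelial genes had such a peak. The wild-type HEK293T RBPJ list also had one at 47.2% of T cell genes. In the knockout ATAC list the share was 19.4% for T cell genes and 26.3% for B cell and myeloid genes. Cells other than the T cell line of the label are a candidate explanation, because the share with a gene-end peak was 13.9% (4.67 to 29.5), against 56.3% of all protein-coding genes, 37.5% of 16 kidney and epithelial genes, 15.8% of the B cell and myeloid genes and 9 of the same 36 genes in the wild-type HEK293T RBPJ list. RAG1, with 37 and 21 reads, and CD8A, with 16 and 12, had a gene-end peak in both ATAC lists and MYB, SATB1 and ZAP70 in wild type only. RAG1, CD8A and MYB also had one in the wild-type HEK293T RBPJ list, so these genes do not tell the label from HEK293T. CD3D, CD3E, CD3G, LCK, CD28 and IKZF1, chosen after their values were seen, were among those with none in the ATAC lists. A peak list gives no level of a transcript, 4 of the T cell genes are also Notch targets, and no biological explanation was tested, so the label is left in doubt and not replaced.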
